A study of Populus trichocarpa with 28 samples.

How the data were processed

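The series measured strand-specific RNA-seq in Populus trichocarpa plants raised from rooted stem cuttings in a greenhouse kept at 20 to 35 C. Per the labels' protocols, all plants were watered to field capacity for 2 months. Control plants stayed at that level. Drought plants were held at 40% of field capacity, for 24 hours in the short-term experiment and for 25 days in the long-term experiment. RNA was extracted with CTAB, a detergent-based method, and treated with DNase I, per the labels' protocols. Libraries were made with stranded TruSeq kits, either from mRNA or from total RNA after removal of ribosomal RNA with Ribo-Zero, and sequenced on an Illumina HiSeq.

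Each of the 28 libraries came with 4 files of whole-number read counts, as the authors deposited them: sense and antisense counts for 41335 genes, and sense and antisense counts for the introns of genes in 33330 entries, of which 109 joined several genes. The submitters' processing notes name TopHat2 2.1.0, HTSeq 0.6.0 and DESeq2, with no role or order. The genome build, the gene annotation and the counting options were not given in the sources used here. File names of root libraries held the word merged, and what was merged was not stated. Closing lines that name no gene stood in 44 of the 56 gene files and were left out of totals and tests. In the sense files that had them, reads in no gene made up 2.53% ± 0.131 of counted alignments in the long-term apex control libraries and 11.5% ± 1.23 in the long-term root total RNA control libraries (mean ± SD, n = 2). The counts are raw, so reads shared between overlapping or near-identical genes were assigned as the authors' counting did, and such genes are uncertain.

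Gene names could not be attached. The reference table at hand held 34621 genes of assembly P.trichocarpa_v4.1, and 0 of the 41335 gene IDs matched it. The gene lists fixed beforehand by product name (abscisic acid, dehydrins, heat shock, osmolytes, aquaporins, photosynthesis, wall loosening, lignin, flavonoids, cell cycle, antioxidants, auxin, jasmonate, pathogenesis-related, ribosomal, circadian clock, secondary wall and meristem) therefore had 0 matched members and gave no result. Genes are given by their IDs alone. The rule fixed before the data were examined was, in the absence of product names, at most 2 genes up and 2 down per comparison, applied to each strand. They were those with the largest fold change among genes with an adjusted p under 0.05, with both drought libraries on the same side of both control libraries, and with a mean of at least 5 CPM (sense) or 1 CPM (antisense). Other IDs in the text were chosen after their values were seen, and this is said beside them.

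Libraries were grouped by term, tissue, library type and watering as labelled, which gave 14 groups of 2 and 7 comparisons of drought with control. The labels do not say whether the libraries of a group came from separate plants, although their titles carry different numbers. If they did not, p-values measure only the spread between libraries. No replicate pair was identical or agreed within counting noise.

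Each comparison was tested with edgeR 4.0.16 (limma 3.58.1, R 4.3.3). Genes passed edgeR's default expression filter (a count of 10 scaled to library size, and 15 counts in total), library sizes were corrected by TMM, and a robust quasi-likelihood model was fitted to the 4 libraries of the comparison. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Antisense and intron counts were tested in the same way with the effective library sizes of the sense counts, so a change is relative to the sense reads of the same library. The antisense-to-sense ratio was tested in a model of both strands with a term for each library and a strand by arm term. Differences between tissues, terms and root library types were tested as interactions. Standard errors of log2 fold changes were the fold change divided by the root of its F value. CPM values are counts scaled by the effective sense library size.

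The fits were tested on simulated counts with known changes before use. In the simulations of the 7 comparisons, 87.0% to 98.0% of 4-fold sense changes and 16.0% to 50.0% of 2-fold ones were called. For antisense counts the shares were 69.0% to 88.0% and 5.00% to 33.0%. For the ratio, 27.0% to 72.5% of 4-fold changes were called, and for interactions 74.5% to 85.0%. Simulated genes varied independently with a common dispersion, and few of them changed, so these shares need not hold in the data.

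Sense totals ran from 20249489 to 67062224 reads per library, antisense totals from 382726 to 2686433, intron sense totals from 251926 to 5949444 and intron antisense totals from 99960 to 1040531. Where an arm had 0 counts of a named gene, the fold is a lower bound against a floor of 3 counts over the group. With 1 to 3 counts, the ratio is given with its 95% exact interval. Both cover counting error only.

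Libraries with the same title number were checked for pairing through the correlation of their deviations from group means. The root mRNA and root total RNA libraries of the same number deviated together, with r = 0.671 in the control arm and 0.735 in the drought arm, so the numbers were taken to pair the root libraries. Across tissues, the 20 correlations ran from -0.01 to 0.299, and 7 were above 0.1. All but the lowest were positive, and young with mature leaves gave 0.299 in the control and 0.221 in the drought arm. The numbers were not taken to pair tissues, although weak pairing is not excluded. Tissue interactions were therefore fitted without a block, and the fits with a block are given among the alternatives.

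Alternatives were no count filter, DESeq2's median-of-ratios size factors, DESeq2 1.42.0 in place of edgeR, a dispersion shared over several comparisons, own library sizes for antisense and intron counts, a 2-fold threshold, genes with antisense counts of at least 5% of sense counts, a block for title numbers, and leaving out each library in turn. Own totals, as written below, are totals corrected by TMM within the antisense or intron counts. Scaling by them takes out a shift common to most genes, even where the plain total changed less. After seeing the data, the comparisons between terms, an apex fit thinned to equal depth, the antisense share without the 10 loci with most antisense reads, and 2 tissue gene groups were added. The tissue gene groups were taken from control libraries alone: mature leaf genes were at least 4-fold higher in mature leaves than in apex (adjusted p under 0.05, mean of at least 5 CPM), and apex genes the reverse. Short-term comparisons used groups defined in long-term controls (1316 and 1359 genes), and long-term comparisons used groups defined in short-term controls (1192 and 1004 genes), so no library entered both. A tissue score per library was the mean log2 CPM of mature leaf genes minus that of apex genes. Groups were tested with camera at a preset correlation of 0.01 and with an estimated correlation, and with fry, over 14 tests each.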

Results

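The study asked which Populus genes respond to drought on the sense and on the antisense strand, in several tissues and after a short or a long water deficit. Sense and antisense reads over genes and introns were counted in 28 libraries. The short-term experiment had apex and mature leaves, both as total RNA. The long-term experiment had apex, young leaves, mature leaves and root as mRNA, and root also as total RNA. Each combination of tissue, term and library type had 2 control and 2 drought libraries. Sense totals per library were 37163762 to 60052682 reads in short-term apex, 32306721 to 43672820 in short-term mature leaves, 20249489 to 29589429 in the long-term shoot tissues, 51376870 to 58352615 in root mRNA and 55712373 to 67062224 in root total RNA. Unless stated otherwise, calls are from edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05.

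The apex after 24 hours of drought changed most broadly on the sense strand among the 7 comparisons. Of 27027 genes tested, 8115 rose and 8720 fell, 62.3% in all, with a median log2 change of 1.16 among the risers and -1.503 among the fallers. Potri.005G098200 had 0 counts in the control libraries and 984 in the drought libraries, at least 409-fold higher. Potri.010G075400 went from 1 count to 869, a ratio of 1084 (95% counting interval 194 to 42860). In the other direction, Potri.012G018300 went from 1633 counts to 0, at least 436-fold lower, and Potri.003G210100 fell by 9.49 on the log2 scale (SE 0.24, adjusted p = 3.08e-05), from 204 ± 29.1 to 0.281 ± 0.0164 CPM (mean ± SD, n = 2). With a 2-fold threshold, 11095 sense genes remained called in short-term apex.

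Apex genes and mature leaf genes, as defined in the long-term control libraries, moved apart in the short-term apex. Of 1354 apex genes tested, 1140 fell and 78 rose, with a median log2 change of -2.37. Of 1261 mature leaf genes tested, 674 rose and 184 fell, with a median of 0.79. At the preset correlation, camera placed apex genes below other genes (adjusted p = 7.14e-59) and mature leaf genes above them (adjusted p = 1.52e-10). Neither call held with an estimated correlation (adjusted p = 0.182 and adjusted p = 0.354), while fry, which tests the direction of the group itself, gave adjusted p = 0.0322 and 0.0446. The tissue score was -2.17 ± 0.254 in the apex control libraries, 1.16 ± 0.066 in the apex drought libraries and 4.08 ± 0.209 in the mature leaf control libraries of the same experiment (mean ± SD, n = 2 each).

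**Figure D1:**
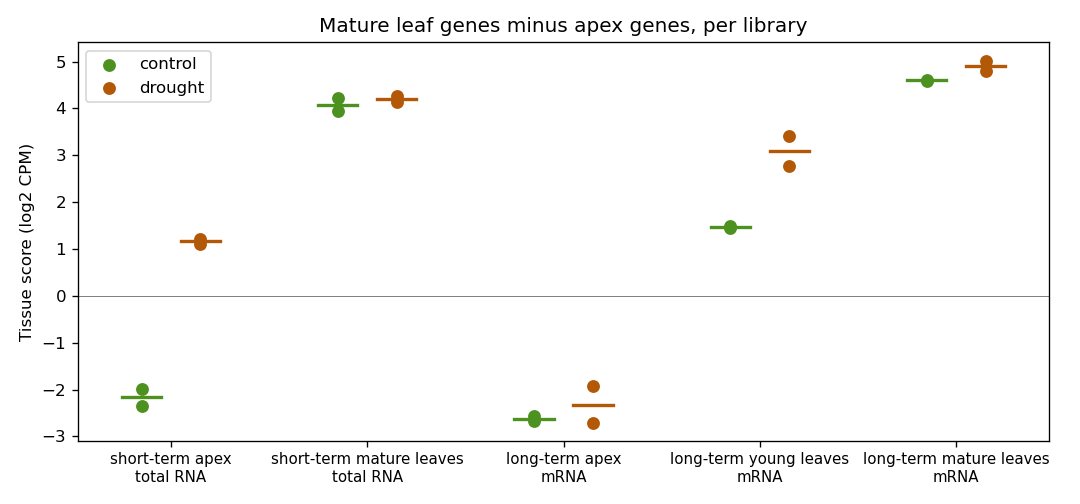
Tissue score of each shoot library (mean log2 CPM of mature leaf genes minus that of apex genes, y axis) by comparison (x axis), with points for libraries and bars for the mean of 2 control or 2 drought libraries. Short-term apex drought libraries lie at 1.11 and 1.21 and long-term young leaf drought libraries at 2.76 and 3.41, all above their controls.

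On the antisense strand of the short-term apex, 1725 of 3651 genes were called, and 1247 of these rose relative to the sense reads. The median antisense change over all tested genes was 0.63 on the log2 scale. When antisense counts were scaled by their own TMM-corrected totals, which takes out a shift common to most genes, 708 rose and 778 fell. Antisense counts of Potri.006G048200 went from 1 to 337, a ratio of 420 (95% counting interval 74.9 to 16650), and those of Potri.002G023900 from 1 to 232, a ratio of 289 (51.4 to 11480). Antisense counts of Potri.001G016900 went from 332 to 1, with 266 times as much in controls (47.5 to 10540), and those of Potri.018G079400 from 202 to 2, with 81.0 times as much (22.1 to 673). The antisense-to-sense ratio rose in 717 genes and fell in 317, or 470 and 468 with each strand scaled by itself. Leaving out control library 19 or 49 lowered the antisense calls to 997 and 923 and the ratio calls to 576 and 533, and without a count filter 559 ratio calls were made.

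Intron reads on the sense strand of the short-term apex rose over 10530 of 18148 genes and fell over 1959. Their median change was 0.86 on the log2 scale relative to the sense reads of genes. TMM correction within the intron counts takes out such a common shift, and with these corrected totals 3903 rose and 4575 fell. The rise reached genes without a sense call. Of 6450 such genes with an intron test, intron reads rose in 4008 and fell in 75. With own TMM-corrected intron totals, 707 rose and 840 fell. Intron reads per 100 sense reads were 9.77 ± 0.189 in control and 11.3 ± 0.373 in drought libraries (mean ± SD, n = 2; exact two-sided permutation p = 0.333, the smallest that 2 against 2 libraries allow). This share includes 17 entries with most intron reads on either strand, picked after the result was seen. Without them, intron sense reads were 47280 and 43250 CPM in control and 78480 and 89480 CPM in drought libraries. The share over all entries thus understates the rise over the others.

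Mature leaves after 24 hours of drought had fewer calls: 2186 of 25054 sense genes rose and 2306 fell. Potri.013G014300 went from 2 counts to 4454, a ratio of 1901 (95% counting interval 526 to 15700). Potri.001G042600 rose by 10.53 on the log2 scale (SE 0.31, adjusted p = 0.000112), from 0.243 ± 0.0872 to 371 ± 28.3 CPM. Potri.017G128400 fell by 5.93 (SE 0.95, adjusted p = 0.0264), from 17.8 ± 10.7 to 0.279 ± 0.323 CPM, and was not called when control library 19 or 49 was left out (adjusted p = 0.103 and 0.116) or without a count filter (adjusted p = 0.0918). Potri.014G022900 fell by 5.81 (SE 0.25, adjusted p = 0.000144), from 15.4 ± 0.0603 to 0.270 ± 0.0235 CPM. The number of sense calls dropped when either control library was left out and rose when either drought library was left out. A fit with an arm of 1 library takes its spread from the other arm, so this does not show which pair the calls rest on. A dispersion shared with the short-term apex gave 6753 calls.

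Antisense counts in short-term mature leaves rose in 251 of 2553 genes and fell in 108, or 184 and 137 when scaled by their own TMM-corrected totals. Potri.014G196900 went from 2 antisense counts to 245, a ratio of 105 (95% counting interval 28.6 to 868), and Potri.002G032600 from 3 to 210, a ratio of 59.8 (20.2 to 292). Potri.002G175400 fell by 4.59 on the log2 scale (SE 0.42, adjusted p = 0.00346) and Potri.005G252600 by 4.29 (SE 0.89, adjusted p = 0.0246). Antisense calls numbered 16 without drought library 35, 10 without drought library 69 and 702 without control library 49. The antisense-to-sense ratio rose in 153 genes and fell in 73, with 6 calls without control library 19, 18 without control library 49 (10 of them among the 226 before), 142 without drought library 69 (104 among them) and 66 without a count filter. Intron sense reads rose over 669 genes and fell over 1124, the opposite balance to the apex. They were even (892 and 879) when scaled by their own TMM-corrected totals. Intron calls numbered 981 without drought library 35 and 526 without drought library 69. The antisense calls of Potri.014G196900 and Potri.002G175400 were lost without drought library 69 (adjusted p = 0.0562 for both), and that of Potri.005G252600 without drought library 35 or 69 (adjusted p = 0.212 and 0.157).

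Drought responses of the apex and mature leaves differed within the short-term experiment. The tissue by drought interaction was called in 7875 of 27796 genes, and in 2382 and 2443 when the libraries of control number 19 or 49 were left out. Fold changes of the tissues correlated at r = 0.54 across genes, which are not independent replicates. Of genes tested in both, 1577 rose in both tissues where independent lists would share 673, 1364 fell in both where 672 would be shared, and 353 went in opposite directions. The tissues share title numbers, so this overlap may not be one of independent samples.

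**Figure D2:**
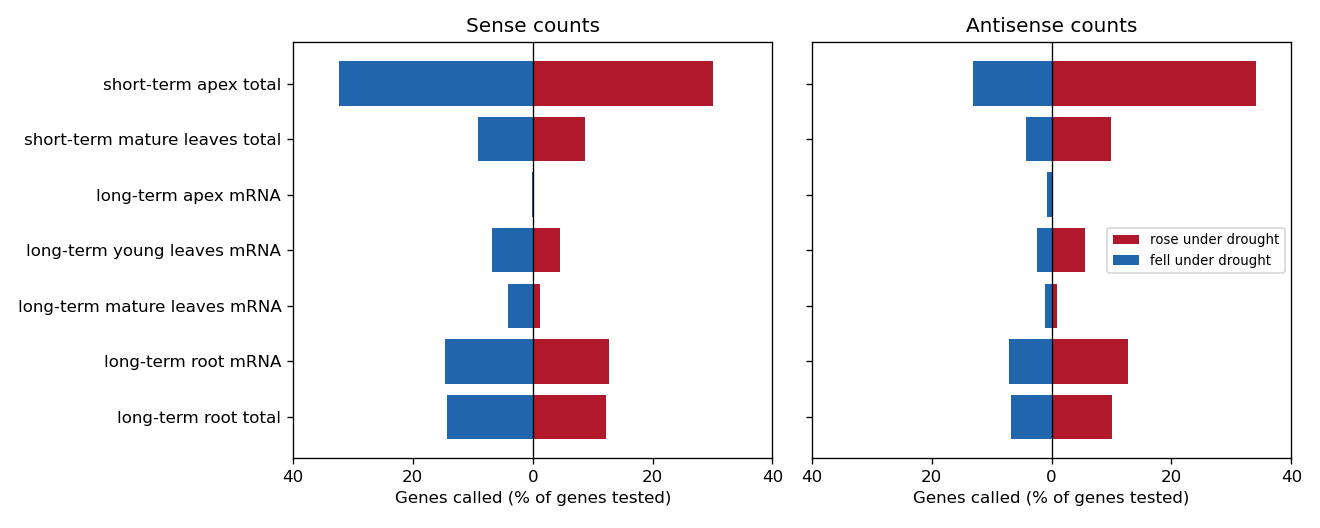
Genes called as risen (right of 0) or fallen (left of 0) under drought, as percent of the genes tested (x axis), on the sense and the antisense strand for each comparison (y axis) of 2 drought with 2 control libraries. Short-term apex leads on both strands with 8115 and 8720 sense genes, and long-term apex has the fewest with 7 and 34.

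After 25 days of drought the apex had few sense calls: 7 of 25068 genes rose and 34 fell. Potri.009G067800 rose by 1.94 on the log2 scale (SE 0.21, adjusted p = 0.0301), from 6.34 ± 1.55 to 24.3 ± 3.44 CPM, and Potri.008G161600 by 1.60 (SE 0.17, adjusted p = 0.0290), from 16.6 ± 2.23 to 50.3 ± 7.49 CPM; neither was called with a dispersion shared among the long-term mRNA libraries (adjusted p = 0.0508 and 0.169). Potri.005G094500 fell by 3.33 (SE 0.21, adjusted p = 0.00478), from 88.9 ± 3.87 to 8.86 ± 2.66 CPM. Potri.001G437400 fell by 3.66 (SE 0.39, adjusted p = 0.0451), from 22.9 ± 2.35 to 1.84 ± 1.24 CPM, and was not called without control library 63 or 70 (adjusted p = 0.224 and 0.0591). DESeq2 called 525 genes in the long-term apex, 102 up and 423 down. Sense calls came to 441 without control library 70, 226 without drought library 68 and 163 without a count filter.

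Antisense counts in the long-term apex rose in 1 of 1559 genes and fell in 12. Potri.004G026100 fell by 2.25 on the log2 scale (SE 0.34, adjusted p = 0.0176) and Potri.010G071500 by 2.11 (SE 0.35, adjusted p = 0.0271); neither was called without drought library 64 or without drought library 68 (adjusted p from 0.0789 to 0.141), and Potri.010G071500 was not called with own antisense totals or a shared dispersion (adjusted p = 0.0581 and 0.0635). Without drought library 64 there were 4 antisense calls, all up and 0 of them among the 13 before, and without drought library 68 there were 0, against 20 without control library 63 and 63 without control library 70. Antisense calls numbered 4 with own antisense totals, 7 with a shared dispersion, 20 by DESeq2 and 45 without a count filter. The ratio test of edgeR called 0 genes, with 77 at an unadjusted p under 0.05. Intron sense reads rose over 1 gene and fell over 6 of 6712. Leaving out control libraries 63 and 70 and drought libraries 64 and 68 in turn gave 12, 94, 28 and 51 intron calls, and 62 were made without a count filter.

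Young leaves after 25 days of drought had 1144 sense genes that rose and 1690 that fell, of 24778. Potri.014G126000 rose by 5.88 on the log2 scale (SE 0.38, adjusted p = 0.00119), from 0.423 ± 0.199 to 24.8 ± 8 CPM, and Potri.013G101000 by 5.34 (SE 0.33, adjusted p = 0.00116), from 5.14 ± 1.57 to 209 ± 62.3 CPM. Potri.006G108100 fell by 6.94 (SE 0.50, adjusted p = 0.00119), from 10.9 ± 0.632 to 0.0761 ± 0.108 CPM. Potri.013G051100 fell by 5.11 (SE 0.78, adjusted p = 0.0458), from 41.2 ± 25.8 to 1.16 ± 0.618 CPM, and was not called without drought library 64 or 68 (adjusted p = 0.380 and 0.251) or without a count filter (adjusted p = 0.130). Apex genes, as defined in the short-term controls, fell in 440 of 972 cases and rose in 7, and mature leaf genes rose in 297 of 1182 and fell in 31. Camera placed both groups apart from other genes at the preset correlation (adjusted p = 1.23e-54 and 8.68e-22) but not with an estimated correlation (adjusted p = 0.182 for both); fry gave adjusted p = 0.0446 for both. The tissue score was 1.48 ± 0.035 in control and 3.09 ± 0.460 in drought young leaves (mean ± SD, n = 2). Sense calls numbered 1841 without drought library 64 and 1833 with a 2-fold threshold.

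Antisense counts in long-term young leaves rose in 84 of 1511 genes and fell in 37, or 48 and 41 when scaled by their own TMM-corrected totals. Potri.013G095400 rose by 3.55 on the log2 scale (SE 0.28, adjusted p = 0.000825). Potri.005G204900 rose by 3.93 (SE 0.53, adjusted p = 0.0120), but was not called without control library 63 or 70 (adjusted p = 0.393 and 0.237). Potri.003G028300 fell by 2.40 (SE 0.32, adjusted p = 0.00851) and Potri.015G148500 by 2.25 (SE 0.35, adjusted p = 0.0108). DESeq2 called 75 antisense genes, and 79 were called without drought library 68. The ratio test of edgeR called 0 genes, with 183 at an unadjusted p under 0.05. Intron sense reads rose over 70 genes and fell over 19 of 6767, or 41 and 42 when scaled by their own totals, with 372 calls without control library 63 and 476 without control library 70, and 305 without a count filter.

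Mature leaves after 25 days of drought had more genes that fell than rose: 957 against 303 of 23503 sense genes. Potri.012G022400 rose by 5.10 on the log2 scale (SE 0.21, adjusted p = 0.00211), from 5.20 ± 0.217 to 178 ± 27.5 CPM, and Potri.010G012100 by 3.64 (SE 0.31, adjusted p = 0.00656), from 70.9 ± 14.2 to 882 ± 241 CPM. Potri.006G141400 fell by 6.90 (SE 0.33, adjusted p = 0.00212), from 125 ± 39.9 to 1.03 ± 0.114 CPM. Potri.006G275900 fell by 6.63 (SE 0.68, adjusted p = 0.0137), from 12.6 ± 7.66 to 0.119 ± 0.0275 CPM, and was not called without drought library 68 (adjusted p = 0.0570). The sense calls ranged from 515 without drought library 68, 722 without drought library 64 and 816 without control library 63 to 2728 without control library 70. DESeq2 called 2250 genes, a shared dispersion 3636 and the test without a count filter 1906.

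Antisense counts in long-term mature leaves rose in 13 of 1435 genes and fell in 16, or 4 and 11 when scaled by their own TMM-corrected totals. Potri.002G150800 rose by 3.38 on the log2 scale (SE 0.50, adjusted p = 0.0205) and Potri.013G042700 by 2.93 (SE 0.55, adjusted p = 0.0345). Potri.010G132400 fell by 3.55 (SE 0.57, adjusted p = 0.0316), and Potri.001G235400 went from 112 counts to 3, with 41.5 times as much in controls (95% counting interval 13.8 to 204). No antisense gene was called without control library 63 (0 by edgeR, with adjusted p of 0.212 to 0.216 for these 4), while 61, 58 and 47 were called without control library 70, drought library 64 and drought library 68. The ratio test of edgeR called 0 genes, with 150 at an unadjusted p under 0.05. With own antisense totals Potri.010G132400 and Potri.013G042700 were not called (adjusted p = 0.0582 for both). Antisense calls numbered 15 with own antisense totals, 138 with a shared dispersion and 97 without a count filter. Intron sense reads rose over 15 genes and fell over 41, with 118 calls when scaled by their own totals and 253 without a count filter. Without control libraries 63 and 70 and drought libraries 64 and 68 in turn, intron calls numbered 156, 421, 99 and 89.

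Roots after 25 days of drought responded alike in both library types. In root mRNA, 3498 of 27499 sense genes rose and 4039 fell, and in root total RNA 3356 of 27628 rose and 3941 fell. Fold changes of the library types correlated at r = 0.96 across 26826 genes. In both, 2763 genes rose and 3237 fell, where independent lists would share 430 and 578, and 0 genes called in both went in opposite directions. These libraries share title numbers and deviate together within arms, so this overlap is not one of independent samples. Potri.012G141300 rose in both, by 7.65 on the log2 scale in mRNA (SE 0.38, adjusted p = 0.00526) from 0.357 ± 0.0881 to 72.6 ± 24.2 CPM, and by 7.46 in total RNA (SE 0.45, adjusted p = 0.00580). Potri.010G141400 rose by 6.66 in mRNA (SE 1.47, adjusted p = 0.0321), but with 895 ± 1119 CPM in drought libraries against 8.86 ± 1.57 in control. It was not called without control library 63 or 70 (adjusted p = 0.150 and 0.154). Potri.001G376200 rose by 6.25 in total RNA (SE 0.69, adjusted p = 0.00946), from 0.211 ± 0.226 to 16.5 ± 5.08 CPM.

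Among the root genes that fell, Potri.003G214800 went from 1306 counts to 2 in mRNA, with 610 times as much in controls (95% counting interval 168 to 5039), and Potri.003G214700 fell by 8.01 on the log2 scale (SE 0.40, adjusted p = 0.00526), from 14.8 ± 3.82 to 0.0552 ± 0.0259 CPM. In total RNA, Potri.005G117000 fell by 7.78 (SE 0.79, adjusted p = 0.00830), from 15.4 ± 10.4 to 0.0673 ± 0.0140 CPM, and Potri.007G015100 fell by 7.24 (SE 0.72, adjusted p = 0.00816), from 10.6 ± 6.70 to 0.0673 ± 0.0140 CPM. In both root library types, fewer sense genes were called when either control library was left out, and also without drought library 68. A fit with an arm of 1 library takes its spread from the other arm, so this does not show which pair the calls rest on. With a 2-fold threshold, 4614 sense genes were called in root mRNA and 4260 in root total RNA. The library type by drought interaction of edgeR was called in 0 of 28567 genes, with 244 at an unadjusted p under 0.05. That is fewer than this threshold would give with no difference at all, and the fit ignored the pairing of these libraries. Its 0 calls therefore do not show likeness. With the title numbers as a block, which the paired deviations of these libraries call for, the interaction was called in 25 genes.

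Antisense counts in root rose in 398 of 3103 genes and fell in 221 in mRNA, and rose in 413 of 4074 and fell in 276 in total RNA. With antisense scaled by its own TMM-corrected totals, 324 rose and 332 fell in mRNA. Potri.005G246100 rose by 5.36 on the log2 scale in mRNA (SE 0.38, adjusted p = 0.00270), from 0.781 ± 0.170 to 32.1 ± 14.3 CPM. Potri.008G141700 rose by 6.21 (SE 0.86, adjusted p = 0.00627) and was not called without control library 63 or 70 (adjusted p = 0.0872 and 0.0651). Potri.004G214100 fell in both library types, by 4.30 in mRNA (SE 0.64, adjusted p = 0.00772) and by 3.92 in total RNA (SE 0.66, adjusted p = 0.0242). The mRNA call was lost without control library 63 or 70 (adjusted p = 0.0797 and 0.0661) and without a count filter (adjusted p = 0.261), and the total RNA call with a shared dispersion (adjusted p = 0.0578). Potri.008G014400 fell by 4.78 in mRNA (SE 0.53, adjusted p = 0.00358). In total RNA, Potri.012G113400 went from 1 count to 225, a ratio of 232 (95% counting interval 41.1 to 9183), Potri.008G086000 rose by 5.88 (SE 0.84, adjusted p = 0.00401) and Potri.003G167100 fell by 3.47 (SE 0.41, adjusted p = 0.000366). Antisense calls in root mRNA numbered 52 without control library 63, 46 without control library 70, 934 without drought library 64 and 369 among genes with antisense counts of at least 5% of sense counts. DESeq2 called 443 antisense genes in root total RNA.

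The antisense-to-sense ratio in root rose in 239 genes and fell in 161 in mRNA, or 201 and 231 with each strand scaled by itself, and rose in 243 and fell in 155 in total RNA. Ratio calls numbered 219 and 169 in mRNA without control library 63 or 70. In total RNA they numbered 189, 241 and 152 without control library 63, control library 70 or drought library 68. Without a count filter they were 137 and 150. Between the root library types, the ratio differed in 1249 of 3335 genes, higher in total RNA for 608 and higher in mRNA for 641. This fit did not use the pairing of the root libraries by title number. Intron sense reads rose over 1327 genes and fell over 707 in root mRNA, or 1227 and 1172 when scaled by their own TMM-corrected totals. In root total RNA they rose over 1743 and fell over 1661. Intron calls in mRNA numbered 753, 891 and 4406 without control library 63, control library 70 or drought library 64, and in total RNA 1952 and 1840 without control library 63 or 70.

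Tissues differed in their response to the long drought. The tissue by drought interaction over the 16 long-term mRNA libraries was called in 5743 of 28724 genes, and in 1615, 2115, 2175 and 1722 when the libraries of number 63, 70, 64 or 68 were left out. Young and mature leaves correlated at r = 0.49 across genes, young leaves and root mRNA at 0.40, and apex and root mRNA at -0.02. In young leaves, mature leaves and root mRNA together, 41 genes rose and 189 fell. No gene was called in the same direction in all 4 long-term mRNA tissues (0 up and 0 down by edgeR), where the apex had 41 calls in all.

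Drought changes differed between the short and the long experiment within apex and within mature leaves, as labelled, although the experiments also differed in library type. In apex, the sampled tissue may differ too. The tissue score under drought was 1.16 ± 0.066 in the short-term and -2.32 ± 0.545 in the long-term apex, against control means of -2.17 and -2.62. In the apex the term by drought interaction, added after the counts of calls were seen, was called in 13364 of 27733 genes, and fold changes correlated at r = -0.09. In mature leaves it was called in 1098 of 25803 genes, with r = 0.36. Of genes tested in both, 413 fell in mature leaves under both terms where independent lists would share 86.1, and 74 rose where 25.9 would be shared. The mature leaf count fell to 207 without control library 19, 233 without control library 49, 442 and 266 without drought libraries 64 and 68, 676 and 663 without control libraries 63 and 70, and 727 without drought library 69, and it was 1793 without drought library 35.

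A few loci held a large part of the antisense reads. The 10 loci with most antisense reads over all libraries, picked after their values were seen, took 65.99% of antisense reads in total RNA libraries and 48.8% in mRNA libraries. Potri.018G115200 alone took 41.5% in total RNA libraries and 0.0985% in mRNA libraries, with 9705731 antisense and 7374 sense reads in all. Potri.013G139800 showed the reverse, with 0.418% and 12.3%. These sets of libraries also differ in tissue and term, so the contrasts are not of library type alone. Potri.013G139800 was the top antisense locus only in some long-term leaf mRNA libraries, with 36.4% of antisense reads in mature leaf drought library 64. Over all loci, antisense reads made up 3.77% ± 0.246 of gene reads in short-term apex controls and 4.29% ± 0.934 in the drought libraries, and the arms overlapped there, in both sets of mature leaves and in root total RNA. Drought means were lower than control means in short-term mature leaves (3.89% against 4.57%) and root total RNA (3.75% against 3.80%). Without these 10 loci, antisense reads made up 1.40% ± 0.0117 of gene reads in short-term apex controls and 1.61% ± 0.186 in the drought libraries (mean ± SD, n = 2). Without them, both drought libraries lay above both controls in every comparison but short-term mature leaves, where the means were 1.13% ± 0.151 and 1.14% ± 0.0442. These shares were compared by exact permutation, where the smallest two-sided p for 2 against 2 libraries is 0.333.

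**Figure D3:**
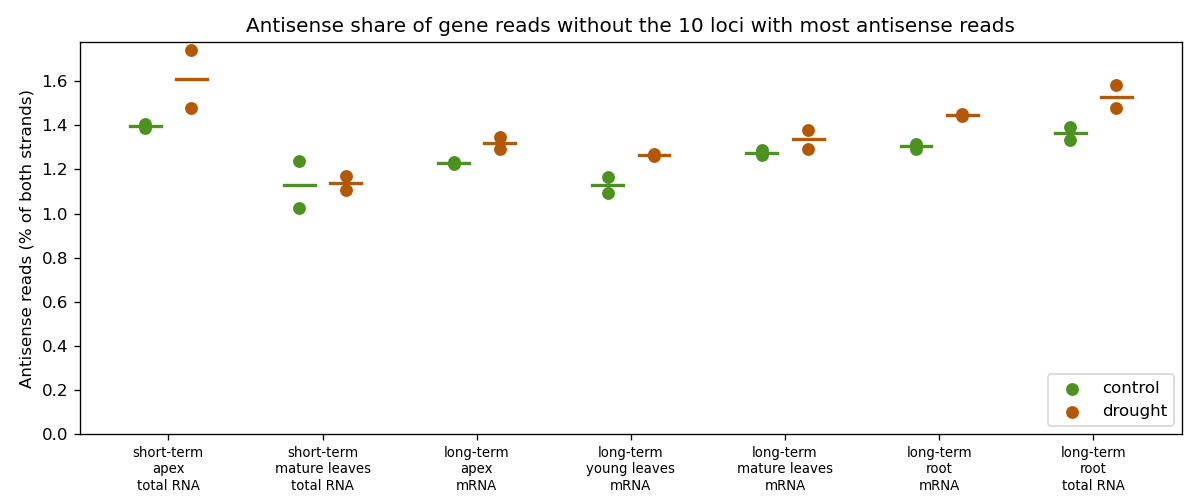
Antisense reads as percent of gene reads on both strands (y axis), without the 10 loci with most antisense reads, for each library (points) and the mean of 2 libraries (bars) by comparison (x axis). In short-term apex the drought mean is 1.61% and the control mean 1.40%, and in short-term mature leaves they are 1.14% and 1.13%.

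Antisense and sense changes of the same gene ran together in all 7 comparisons. Both strands come from the same 4 libraries, so library differences other than drought can also raise the correlation r. No r without drought was computed, and r was highest in long-term apex, where only 7 sense genes rose and 34 fell. Across genes, which are not independent replicates, r was 0.39 in short-term apex, 0.27 in short-term mature leaves, 0.61 in long-term apex, 0.57 in young leaves, 0.54 in mature leaves, 0.48 in root mRNA and 0.39 in root total RNA. Among genes with antisense counts of at least 5% of sense counts it was 0.305 in root mRNA and 0.241 in root total RNA. In short-term apex, 828 genes were called on both strands. Of these, 412 rose on both, 175 fell on both, 182 rose on antisense and fell on sense, and 59 did the opposite. In root mRNA, 254 of 283 genes called on both strands went in the same direction, and in young leaves 49 of 51.

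**Figure D4:**
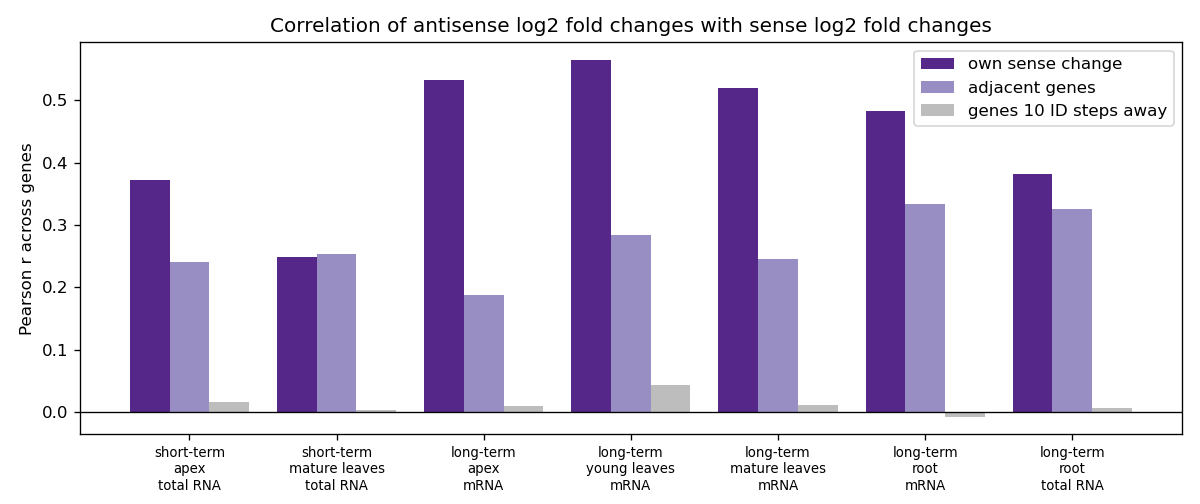
Pearson correlation across genes (y axis) of antisense log2 fold changes with the gene's own sense change, with the mean sense change of genes adjacent by ID number, and with that of genes 10 ID steps away, by comparison (x axis). The median of the 7 comparisons is 0.482 for the own sense change, 0.254 for adjacent genes and 0.01 for genes 10 steps away.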

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

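The comparisons between terms, the fits of intron antisense counts, the tests of the intron rise and the tests of adjacent genes within single comparisons were chosen after the result was seen. The bound used for mature leaf libraries under an apex label was also set after the value was seen.

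The response to drought differed between tissues in the long-term experiment (interaction called in 5743 genes by edgeR, Benjamini-Hochberg adjusted) and in the short-term experiment (7875 genes). It differed between the short and the long drought in apex (13364 genes) and mature leaves (1098 genes), where the experiments also differ in library type. In apex they may also differ in sampled tissue, as described below. In root, where both types were made, library type by drought was called in 0 of 28567 genes by edgeR (244 at an unadjusted p under 0.05, 25 with the title numbers as a block) and fold changes correlated at r = 0.96, but the shoot tissues had no such pair of libraries. The fit with 0 calls ignored the pairing of root libraries, and 244 is fewer than that threshold gives with no difference. It therefore cannot argue against an effect of library type. Root libraries of the same title number also deviated together within arms (r = 0.671 and 0.735), which raises that 0.96 whatever the drought response. Antisense reads over introns, whose gene-wise changes the report does not give, rose under drought over 301 of 808 genes in short-term apex (123 fell) and 52 of 546 in short-term mature leaves (16 fell). In the long-term mRNA libraries they rose over 1 gene in apex (1 fell), 11 in young leaves (8 fell), 10 in mature leaves (9 fell) and 96 in root (53 fell), and in root total RNA over 112 (66 fell).

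In the short-term apex, 62.3% of tested sense genes were called, and the drought change ran along the difference between mature leaves and apex in the long-term controls (r = 0.565 over 24740 genes), so the drought apex libraries may carry more of a mature leaf profile. The change correlated about as well with drought changes in root mRNA (r = 0.561), root total RNA (0.566) and short-term mature leaves (0.543). It did so less with young leaves (0.471), long-term mature leaves (0.169) and long-term apex (-0.09). An r of about 0.565 was thus not reached with that difference alone. It neither singles out leaf maturity nor argues against it, since these drought changes and that difference were not separated. A shift along the difference between mature leaves and apex alone would leave genes with less than 0.5 log2 of it mostly uncalled, yet 51.23% were called. These genes were set in long-term mRNA controls, and genes highest in tissue between apex and mature leaf would count among them. A change of sampled tissue is therefore not excluded as the whole cause. Mature leaf libraries under an apex label were argued against by tissue scores of 1.208 and 1.115, the higher of which lay 2.73 below the lowest mature leaf library. The bound written beforehand, scores nearer the apex controls, was not met, as both lay slightly nearer the mature leaf mean. A mixed sample, apex pieces with more expanded leaf, and a drought response that matures the apex all stay open.

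Antisense and sense changes of a gene ran together in all 7 comparisons. Both strands come from the same 4 libraries, so library differences other than drought can raise r, and no r without drought was computed. The highest r, 0.605, was that of long-term apex, where only 7 sense genes rose and 34 fell. Sense reads counted on the wrong strand would act mostly where antisense counts are a small part of sense counts. Among genes with antisense of at least 5% of sense the median r was 0.305, with the lowest, 0.187, in short-term mature leaves (0.273 over all genes). With this limit r fell in short-term apex (0.385 to 0.263), root mRNA (0.480 to 0.305) and root total RNA (0.392 to 0.241). It changed little in long-term mature leaves (0.543 to 0.533) and rose in long-term apex (0.605 to 0.732) and young leaves (0.569 to 0.648). Such reads are thus not the whole cause, but a part from them stays open. In genes with at least 5000 sense counts, the median antisense count per library was 0.0118% to 0.0625% of the sense count, highest in a single drought library each of short-term apex (0.0625% in 35, 0.0196% in 69, controls 0.0184% and 0.0197%) and root mRNA (0.0618% in 64, 0.0360% in 68, controls 0.0384% and 0.0250%). Antisense changes correlated less with the mean sense change of genes adjacent by ID number (median r of 0.254) than with the gene's own (0.482). That mean can include neighbours that give no antisense reads, which lowers r. The lower r therefore cannot argue against reads of adjacent genes. It was not lower in short-term mature leaves (0.254 against 0.248), and was 0.325 against 0.381 in root total RNA. Antisense changes also followed adjacent genes more closely than own sense changes did, as in short-term apex (0.241 against 0.066). Only long-term apex differed (0.188 against 0.199). Reads of adjacent genes thus stay open as a cause in all 7 comparisons. Shared regulation of both strands under drought stays a hypothesis, and overlapping genes on opposite strands were not examined here.

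Intron sense reads rose broadly in the short-term apex. Genomic DNA would add reads to both strands alike, but without the 17 entries with most intron reads the antisense-to-sense ratio of the added reads was 0.004881 (189 against 38710 CPM), and with them 0.1053 (1155 against 10960 CPM, antisense totals of the arms overlapping). A single library did not make the rise, with median log2 changes of 0.695 and 0.869 in the drought libraries. Intron counts that rose were also higher in mature leaf controls than in apex controls (median 0.323), so a shift of tissue profile may contribute, although this test shares the apex controls with the rise. Over all tested genes that difference was 0.112 against a drought change of 0.856, so a shift toward the mature leaf profile alone falls short of it. Other changes of sampled tissue were not tested, and more unspliced RNA under drought stays open as a hypothesis.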

How the results depend on the processing

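Thinning to equal depth, the share without the 10 loci with most antisense reads and the comparisons between terms were chosen after the result was seen. Of 169 counts, shares and correlations recomputed under other settings, 123 stayed within 1.5 times or 1 SD and 46 moved. Of 294 recomputed values of named genes, 284 kept their direction and side of the threshold and 10 lost the call. With a library or title number left out, 85 of 172 counts and correlations stayed and 87 moved, and 27 of 216 named-gene calls were lost. No named gene or strand correlation reversed (0 of these), while counts and shares had no label for a reversal. The drought minus control antisense share did change sign without the 10 loci in 2 comparisons. It went from -0.6791 to 0.004761 percentage points in short-term mature leaves and from -0.04546 to 0.1655 in root total RNA. The causes were not tested, except that a stricter threshold or fewer genes leave fewer calls by construction.

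The 2-fold threshold gave 11095 sense genes in short-term apex, 1833 in young leaves, 4614 in root mRNA and 4260 in root total RNA. Overlaps at that threshold were 2.21 times those of independent lists for long-term apex and root mRNA (2 genes rose and 4 fell in both, 6 went opposite ways), 1.52 for long-term apex and root total RNA (1, 3 and 7 genes), 4.95 and 5.32 for long-term mature leaves with root mRNA and root total RNA, and 9.86 between the root library types. DESeq2 called 525 sense and 20 antisense genes in long-term apex, 2250 sense genes in long-term mature leaves, 75 antisense genes in young leaves and 443 in root total RNA. A shared dispersion gave 6753 sense genes in short-term and 3636 in long-term mature leaves, 138 antisense genes in the latter and 7 in long-term apex.

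Without a count filter, long-term apex had 163 sense, 45 antisense and 62 intron calls, and long-term mature leaves 1906, 97 and 253. Young leaves had 305 intron calls. Ratio calls then were 559 in short-term apex, 66 in short-term mature leaves, 137 in root mRNA and 150 in root total RNA. Own library sizes gave 4 antisense calls in long-term apex and 15 in long-term mature leaves, with 118 intron calls there.

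Among genes with antisense of at least 5% of sense, r between strands was 0.263 in short-term apex, 0.187 in short-term mature leaves, 0.732 in long-term apex, 0.648 in young leaves, 0.305 in root mRNA and 0.241 in root total RNA, with 79 antisense calls in young leaves and 369 in root mRNA. The drought minus control antisense share, in percentage points, was 0.3063 in long-term apex and 0.6631 in young leaves over genes and introns, and without the 10 loci 0.0902 in long-term apex, 0.1378 in young leaves and 0.1422 in root mRNA. A block for title numbers gave 25 genes for root library type by drought. The same block across tissues, which the numbers were not taken to pair, gave 6867 (long-term, 5562 shared) and 8785 (short-term, 7547 shared) interaction genes. Thinned to equal depth, short-term apex had 16692 sense calls, 16464 of them shared with the 16835 before.

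With a library left out, an arm of 1 library was assumed to vary like the others. Sense calls then ranged from 92 to 6775 in short-term mature leaves, 38 to 441 in long-term apex, 1841 to 2555 in young leaves, 515 to 2728 in long-term mature leaves, 1168 to 8858 in root mRNA and 1773 to 7056 in root total RNA. Antisense calls ranged from 923 to 2322 in short-term apex, 10 to 702 in short-term mature leaves, 0 to 63 in long-term apex, 79 to 173 in young leaves, 0 to 61 in long-term mature leaves and 46 to 934 in root mRNA. Ratio calls ranged from 533 to 1520 in short-term apex, 6 to 179 in short-term mature leaves, 169 to 451 in root mRNA and 152 to 479 in root total RNA. Intron calls ranged from 526 to 2337 in short-term mature leaves, 12 to 94 in long-term apex, 80 to 476 in young leaves, 89 to 421 in long-term mature leaves, 753 to 4406 in root mRNA and 1840 to 4100 in root total RNA.

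Strand correlations ranged from 0.326 to 0.393 in short-term apex, 0.204 to 0.275 in short-term mature leaves, 0.542 to 0.579 in long-term apex, 0.529 to 0.603 in young leaves, 0.494 to 0.577 in long-term mature leaves, 0.455 to 0.475 in root mRNA and 0.344 to 0.379 in root total RNA. Interactions ranged from 1615 to 2175 (long-term tissues), 2382 to 7000 (short-term tissues) and 207 to 1793 (terms in mature leaves). Alternatives for the gene lists, and for genes without an overlapping opposite-strand gene, were not run, since no list had a matched member and gene positions were not used here. The effect of depth on antisense calls was not tested.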

Other observations

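Many apex genes also fell in roots. Of the apex genes defined in short-term controls, 407 of 895 fell and 41 rose in root mRNA after 25 days of drought, and 405 of 886 fell and 37 rose in root total RNA, with medians of -0.89 and -0.91 on the log2 scale. Camera with an estimated correlation gave adjusted p = 0.328 for both and fry adjusted p = 0.0588 for both, so neither called the group, against adjusted p = 2.94e-18 and 7.91e-20 for camera at the preset correlation. In long-term apex 1 of 1085 mature leaf genes rose and 17 of 1000 apex genes fell (fry adjusted p = 0.601 and 0.493). In long-term mature leaves both groups fell more than they rose, with 107 against 22 mature leaf genes and 80 against 16 apex genes (fry adjusted p = 0.0446 for both). In short-term mature leaves 259 mature leaf genes fell and 148 rose (fry adjusted p = 0.0446), and 199 apex genes fell and 90 rose (fry adjusted p = 0.128). In root, mature leaf genes rose in 265 cases and fell in 146 in mRNA, and rose in 238 and fell in 147 in total RNA (fry adjusted p = 0.0883 and 0.127). None of the 14 tests passed camera with an estimated correlation (lowest adjusted p = 0.182). The tissue gene groups, the test in young leaves, the scaling of introns by their own totals for genes that fell and the restriction to splits that part pairs were chosen after the result was seen.

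Intron and sense changes mostly ran together in the short-term apex (r = 0.875 over 17705 genes), but they parted in some genes. Of 8137 genes called on both, 7046 went in the same direction. Of 5595 genes whose sense counts fell and whose introns were tested, intron reads rose in 1080. In root mRNA this held for 2 of 1573 genes and in short-term mature leaves for 1 of 1069. The apex count includes the rise common to its introns. With intron counts scaled by their own TMM-corrected totals, the count was 84 in short-term apex, 1 in root mRNA and 0 in short-term mature leaves.

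A hypothesis is that young leaves under the long drought carry a more mature profile. The drought change in young leaves correlated at r = 0.565 across genes with the difference between mature leaves and apex in the short-term controls, and both drought libraries had higher tissue scores than both controls. Scores rose in this way in roots too, from a mean of -0.798 to 0.142 in mRNA and from -0.656 to 0.296 in total RNA. A higher score is thus not particular to leaves. In roots the correlation with that difference was lower, at r = 0.220 in mRNA and 0.227 in total RNA. Of axis-neutral genes, those with less than 0.5 log2 difference between these tissues, 4.57% were called in young leaves. The sampled leaf position was not given in the sources used here, so older leaves in the drought samples could give the same shift.

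The antisense-to-sense ratio differed between root mRNA and root total RNA in 1249 genes, in a fit that did not use the pairing by title number. Without a term for drought, the split by library type gave 700 calls, and of the 35 splits of the 8 root libraries into 4 and 4, only 1, this split, gave as many. The highest other split, by drought arm, gave 244. Since the title numbers pair these libraries, the real split compares with the 8 splits that part all 4 pairs, where the highest other gave 0 calls, and 8 splits are too few for a share under 0.05.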
